A study of Homo sapiens with 8 samples.

How the data were processed

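The series held 8 libraries of primary human granulosa/lutein cells, 4 from PGR immunoprecipitation and 4 inputs. Groups were taken from the sample titles, which gave 1 control and 3 hCG libraries of each kind at 12 h. The peak names inside the lists carry sample numbers that differ from the replicate numbers in the titles, while their treatment letters match, so each list was taken as that of the sample it was deposited with. Only the 4 immunoprecipitated libraries came with peak lists, and the input libraries were not analysed here on their own. bcl2fastq 2.20, BWA 0.7.17-r1188, MACS2 2.2.7.1 and the build GRCh38 are named in the submitters' processing notes, without their settings. The authors deposited 1 peak list per library in the layout MACS2 writes, so peaks were called per library and not on pooled replicates.

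Each deposited peak carries the fold enrichment, which was made by the authors. It is a linear ratio of the pileup at the summit to the local background, after MACS2 adds 1 to both. The added 1 lowers the fold most where the background is low. A given fold threshold is therefore stricter at the lowest background of the control and hCG replicate 3 than in the other libraries. The authors also deposited the −log10 p and the −log10 q of each summit, both as MACS2 writes them. The score column the authors deposited equals the whole part of 10 times the −log10 q and added nothing further. Start, end and summit positions were deposited as 0-based coordinates and are given here 1-based. The smallest −log10 q in the lists was between 1.31 and 1.33, just above the value for q = 0.05. Peaks are absent from a list when they miss this threshold, so a missing peak sets no upper limit on binding, and more reads give more peaks past it.

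Peaks on chromosomes 1 to 22 and X were kept. Between 65 and 103 peaks per library, 0.226% to 1.61% of each list, lay on other sequences and were left out. Each list gave every interval once, with a single summit. Peaks of the 4 libraries were merged into regions at an overlap of 1 bp, and a region was assigned to every library with a peak in it. A region's fold in a library was that of its highest peak. Fold and −log10 values were used to describe, rank or filter peaks within a list. Regions were ranked by their lowest fold over the lists concerned, and no fold was compared between libraries by a ratio. Overlaps were set against 100 random placements, which moved all peaks of a library together around each chromosome. These were not kept out of assembly gaps, which lowers the share of random positions inside genes. Shares carry exact binomial intervals at 95%, which cover counting error only.

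Read depth was solved from the lists. Fold and −log10 p of a peak give the pileup at its summit and the local background, and the pileup came out within 0.05 of a whole number for 100% of the peaks in each library. The lowest background was 1.92 in the control and 3.45, 3.32 and 1.56 in hCG replicates 1, 2 and 3. Divided by the smallest peak width (166, 194, 199 and 216 bp), which MACS2 sets to the fragment length by default, it gave 11.6, 17.8, 16.7 and 7.20 reads per kb of effective genome. The median pileup behind a peak was 13 reads in the control and 23, 21 and 22 in the hCG replicates. To compare lists at one depth, pileups and backgrounds of a deeper library were thinned at random to the depth of another, with 100 draws and a single −log10 p threshold of 3.95 for both. This treats each peak at its own summit and cannot restore peaks below the original threshold.

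Gene positions came from a table of RefSeq gene intervals on GRCh38.p14, with 19970 protein-coding genes tested. The table has no strand, transcripts or exons, and no genome sequence was used here. The planned windows around transcription start sites were therefore replaced by the gene interval plus 50 kb on both sides, and the planned promoter class by a region midpoint within 1 kb of either end of a coding gene. The planned searches for the progesterone response element, other motifs and 6-base words, and the filter on repeats, were not run. The 18 gene lists were PGR-linked ovulatory genes, steroid receptor response genes, steroidogenesis and cholesterol, the prostaglandin pathway, EGF-like factors and cumulus expansion, matrix proteases and inhibitors, angiogenic and vasoactive factors, cytokines and inflammatory genes, ovulatory transcription factors, gonadotropin and cAMP signalling, SOX9-linked genes, markers of leukocytes, endothelium and epithelium, hepatocyte and neuronal genes, ribosomal protein genes and olfactory receptor genes. In these lists 18 genes stood in more than 1. Each list was compared with 10000 random lists matched on gene length and on the density of coding genes in 25 bins, a finer match than planned because whole gene intervals favour long genes. This is a permutation of list membership within bins. Its p is two-sided and was adjusted by Benjamini and Hochberg over the 18 lists. Open chromatin was not matched, and neighbouring genes can share a region.

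Named genes followed a rule fixed before the data were examined. SOX9 and PGR are always given. From each list up to 3 members are named, those with the highest value of the lowest fold over the 3 hCG lists, and 1 member without any peak. The 10 strongest regions without a control peak, the 10 strongest of all 4 libraries and the 5 strongest of the control alone are named by the nearest coding gene. A few items that this rule would name are not reported here. Further members named within a list were chosen after their values were seen. The group comparisons, the alternatives with a stricter −log10 q or fold, lists of equal length, summits within 200 bp, 50% of a control peak covered, 2 of 3 hCG libraries, each hCG replicate left out, gene windows of 10 kb and 100 kb and gene ends at 5 kb were also fixed then. The thinning, the windows of 50 kb from gene ends alone and the removal of regions whose local background exceeded 5 times the lowest of a library were added later.

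Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Pileup solving and merging were tested on simulated data, and the list test on made-up gene lists over the deposited peaks. All of 4893 simulated pileups were recovered (100%), and the simulated regions of each class were counted exactly. Of random lists of 20 genes, 2.25% had p under 0.05, among 19970 genes. Of lists with 15 planted members, picked from genes with a region nearby, 100% did. The random lists were drawn from all genes, so they do not give the error rate for lists whose members share regions.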

Results

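Chromatin immunoprecipitation with an antibody against the progesterone receptor (PGR), followed by sequencing, was used to map PGR-bound DNA in primary human granulosa/lutein cells. These are among the hormone-producing cells of the ovarian follicle. Human chorionic gonadotropin (hCG) acts on the luteinizing hormone receptor and stands in culture for the ovulatory gonadotropin surge. Cells were kept for 12 h with hCG, giving 3 ChIP libraries, or without it, giving 1 control ChIP library. Each of the 4 had an input library, and peaks were called separately in each ChIP library. The peak lists held 5484 peaks in the control and 32369, 42363 and 9652 peaks in hCG replicates 1, 2 and 3. Read depth, solved from the lists themselves, was 11.6 ChIP reads per kb of effective genome in the control against 17.8, 16.7 and 7.20 in the hCG libraries. Per-peak fold enrichments below are the authors' values and serve to describe and rank peaks within 1 list. Regions are ranked by their lowest fold over the lists concerned, and no fold is compared between libraries by a ratio. The labels do not say whether the 3 hCG libraries came from separate donors or cultures, so the spread between them may be technical.

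**Figure D1:**
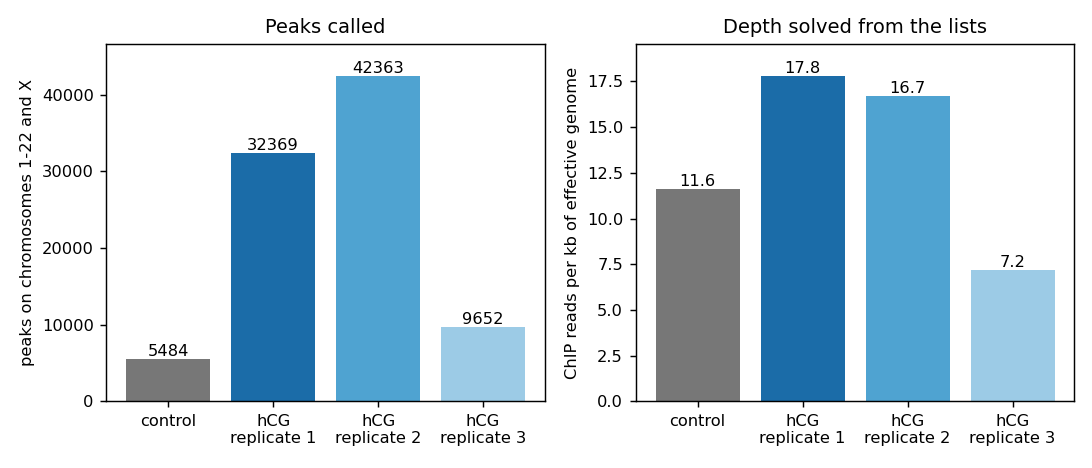
The left panel plots peaks called on chromosomes 1 to 22 and X in each of the 4 PGR ChIP libraries, and the right panel plots ChIP reads per kb of effective genome solved from each list; each bar is 1 library. The control list is the shortest at 5484 peaks, while the lowest depth, 7.20 reads per kb, belongs to hCG replicate 3.

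The title given to the series names SOX9, a transcription factor of gonad and cartilage development, as a gene downstream of PGR. A region 23.8 kb outside the SOX9 gene (chromosome 17, 72149690 to 72150761, GRCh38) held a peak in all 4 libraries. Its highest peak had a fold enrichment of 8.21 in the control list and of 35.5, 33.7 and 46.2 in the lists of hCG replicates 1, 2 and 3. A weaker region close by, 25.3 kb from the gene (72151450 to 72152078), held peaks of 8.09, 6.83 and 5.87 fold in the hCG replicates and none in the control. At PGR itself (chromosome 11, 101029624 to 101129813) no region within 50 kb was shared by all 3 hCG libraries. The 7 regions found there came from hCG replicates 1 and 2 alone, with fold enrichments between 2.27 and 6.07. ZBTB16, a zinc finger repressor known as a target of steroid receptors, carried 11 regions of all 3 hCG libraries, 5 of which also held a control peak. The strongest lay inside the gene (chromosome 11, 114178516 to 114180811), at 21.7 fold in the control list and 30.8, 43.2 and 26.6 fold in the hCG lists.

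**Figure D2:**
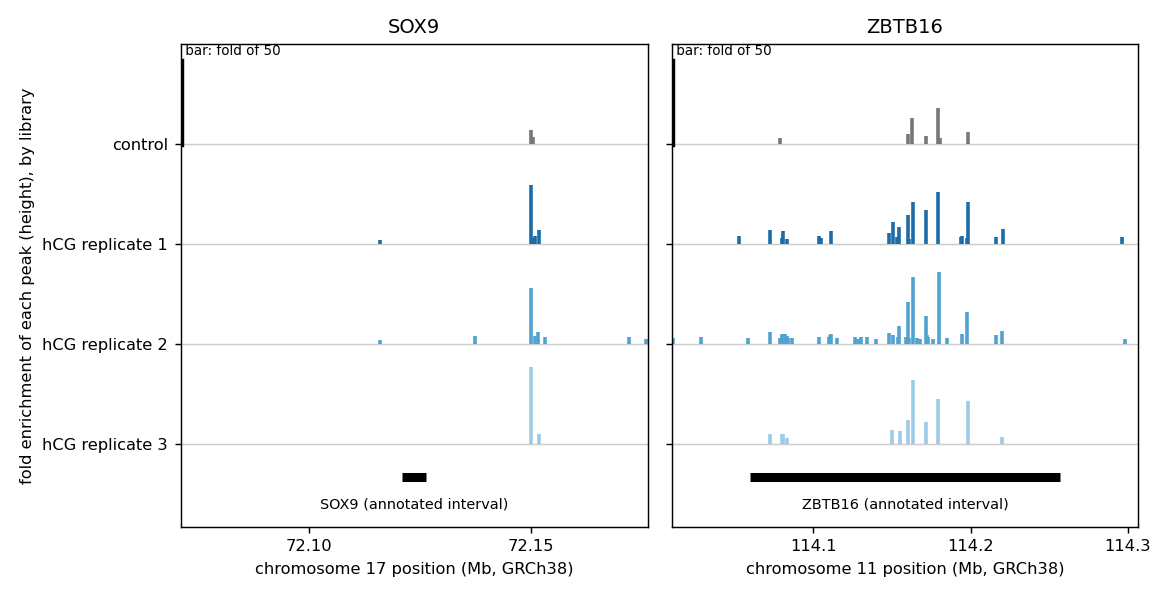
Each panel maps the peaks around one gene, SOX9 on chromosome 17 and ZBTB16 on chromosome 11 (GRCh38 position in Mb on the horizontal axis); every library has its own line, the height of a bar is the fold enrichment of one peak in that library's list, and the thick bar marks the annotated gene interval. Peaks at the region 23.8 kb from SOX9 and at the main ZBTB16 region stand in all 4 lists.

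How many PGR-bound sites were called with and without hCG was the first comparison. Sites near TEK, the angiopoietin receptor, HSD3B2, an enzyme of progesterone synthesis, and CCL20, a chemokine, were called in all 3 hCG libraries and not in the control, although 2 other regions with a control peak, 1 of them control-only, lay within 50 kb of HSD3B2. Sites in or near ZBTB16, CYP19A1, the aromatase gene, and FKBP5, a co-chaperone of steroid receptors, were called in all 4. The hCG libraries held 28128 ± 16763 peaks (mean ± SD, n = 3), 5.13 times the 5484 of the single control. The ratios were 5.90, 7.72 and 1.76 for the separate hCG replicates. The control list was shorter than all 3, but in raw list length replicate 3 was closer to the control than to the other hCG libraries. Brought to the read depth of the control at one threshold, hCG replicates 1 and 2 still gave 27145 ± 56.0 and 34644 ± 62.7 peaks (mean ± SD of 100 random thinnings), 4.95 and 6.32 times the control. Replicate 3 had 62.1% of the control's depth, and the control thinned to that depth gave 4014 ± 25.5 peaks, so that replicate 3 held 2.40 times as many. Thinned to the same depth, replicates 1 and 2 gave 2.23 and 2.50 times the peaks of replicate 3. With 1 control library there was no replicate check and no test, since the smallest one-sided p that an exact permutation of 1 against 3 libraries can give is 0.25. At a −log10 q of at least 5 the control kept 1106 peaks and the hCG libraries 16734 on average, and at a fold of at least 5 these became 1482 and 8782. The fold threshold was stricter for the control and replicate 3, whose lowest backgrounds were 1.92 and 1.56, against 3.45 and 3.32 in replicates 1 and 2.

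The hCG replicates were then compared with each other. Peaks near IL1R1, an interleukin-1 receptor (chromosome 2, 102047997 to 102049317), and near CNTN3, a neural adhesion molecule (chromosome 3, 74643407 to 74644325), were among the strongest in all 3 lists. Their fold enrichments were 61.3, 77.9 and 104 for IL1R1 and 74.0, 74.9 and 90.4 for CNTN3 in replicates 1, 2 and 3. Merging the peaks of all 4 libraries gave 60157 regions, of which 7757 held a peak of all 3 hCG libraries, 10954 of exactly 2 and 38277 of 1. Of the hCG replicate 3 peaks, 86.8% (95% exact binomial interval 86.2 to 87.5, counting error only, as for every interval here) overlapped a replicate 1 peak and 86.7% a replicate 2 peak. In the reverse direction 25.6% of replicate 1 and 19.5% of replicate 2 peaks overlapped replicate 3. Among replicate 1 peaks, 7818 overlapped both other lists, against a mean of 0.740 and at most 4 in 100 random placements. Agreement followed peak strength. In the strongest quintile of each list, 81.2%, 68.4% and 99.5% of the peaks of replicates 1, 2 and 3 overlapped both other hCG lists, and in the weakest quintile 2.29%, 1.51% and 53.6% did. Without hCG replicate 3, the shortest hCG list, the number of regions in every remaining hCG library was 17834. It was 4427 with a fold of at least 5, 3546 with lists of equal length, and 18711 with 2 hCG libraries required in place of 3.

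**Figure D3:**
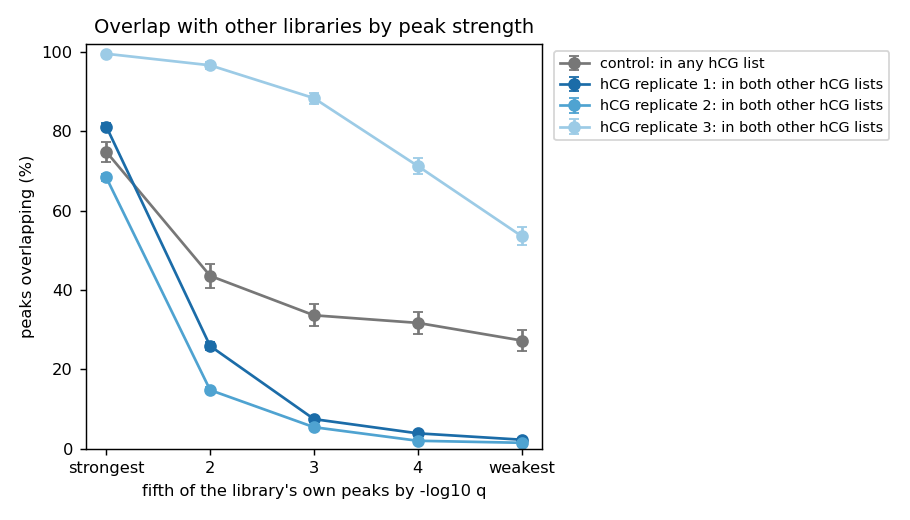
The share of peaks that overlap other lists is plotted, in percent with 95% exact binomial intervals, against the quintile of each library's own peaks by −log10 q; control peaks are set against any hCG list, and the peaks of each hCG replicate against both other hCG lists. The share falls from the strongest to the weakest quintile in all 4 libraries, for the control from 74.8% to 27.3%.

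Regions bound in all 3 hCG libraries and without a control peak answer what was called with hCG alone. TEK held the strongest of them (chromosome 9, 27183560 to 27184361, inside the gene), at 60.0, 53.7 and 73.2 fold in hCG replicates 1, 2 and 3. The next in rank by their lowest fold of the 3 lists were inside GPR135, an orphan receptor gene (chromosome 14, 59453945 to 59454544), AOAH, which encodes an enzyme that inactivates lipopolysaccharide (chromosome 7, 36686508 to 36687071), and UBXN10 (chromosome 1, 20192185 to 20193191). Others among the 10 strongest lay in or nearest to CAMK1G, NCOA2, a nuclear receptor coactivator, TMEM37, ANXA2 and ANO4, and the lowest fold in any of their lists was 35.5. In all, 6668 of the 7757 regions had no control peak. Regions of this kind lay inside ADAMTS9, a matrix protease (32.9, 27.0 and 29.3 fold), and PDE4B, a cAMP phosphodiesterase (28.3, 28.2 and 17.6 fold). Others lay inside ABCC4, a prostaglandin exporter (23.2, 23.0 and 32.1 fold), and 49.3 kb from SLCO2A1, a prostaglandin transporter (22.2, 25.4 and 21.1 fold). Such a region lay within 50 kb of 32.7% of all coding genes. The matrix, cAMP and prostaglandin lists that hold these genes did not pass for such regions (ratios 1.30, 0.693 and 1.25). Other regions near ABCC4 and PDE4B did hold control peaks, 3 and 1 of them. TNFAIP3, an inhibitor of NF-kB signalling, had 5 such regions and no control peak, and DUSP1, a phosphatase of MAP kinases, likewise had 5. Regions with a control peak were stronger in each hCG list, with median folds of 13.1, 14.3 and 10.7 against 6.75, 6.59 and 6.26 in the regions without one. Their median −log10 q was 72.2, 74.5 and 27.7 against 24.5, 20.8 and 10.7 (two-sided permutation test of mean ranks of −log10 q, 100000 resamples over regions, p = 1e-05 in each library, the smallest it can give). Of the strongest quintile of the 7757 regions, 36.3% (33.9 to 38.7) held a control peak, and 989 of the 1552 did not; in the weakest quintile 4.84% (3.82 to 6.02) held one. Absence from the single control list was not replicated. The number of regions without a control peak was 16266 without hCG replicate 3, 3925 at a fold of at least 5, 2755 with lists of equal length, and 17105 with 2 hCG libraries required.

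**Figure D4:**
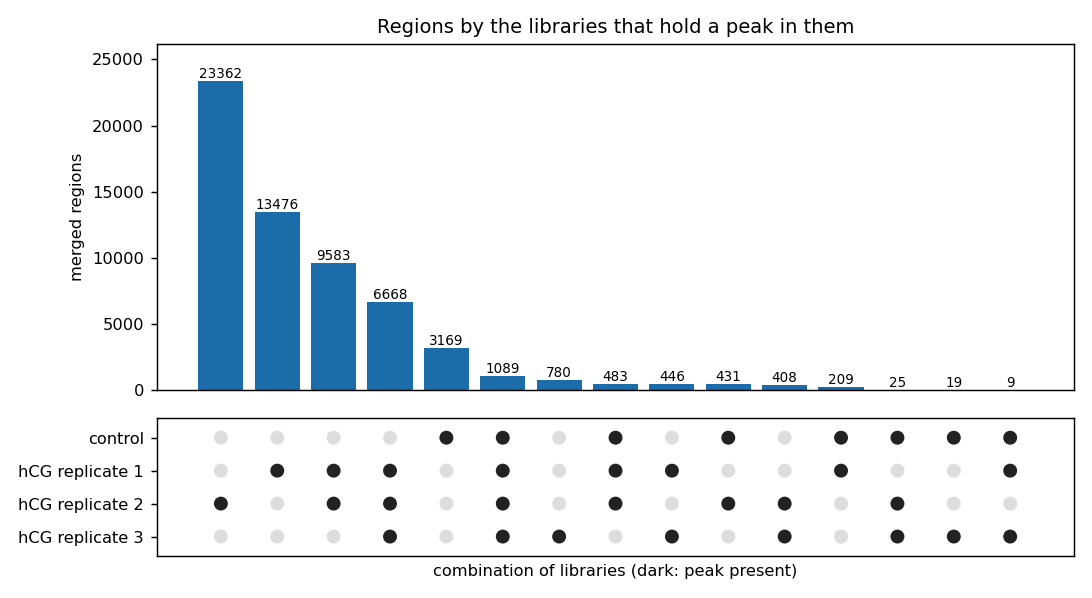
Bars count the merged regions for each combination of libraries, and the dark points under a bar mark the libraries that hold a peak in those regions. The combination of all 3 hCG libraries without the control counts 6668 regions, all 4 libraries 1089, and the control alone 3169.

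Whether sites called without hCG remained among the sites called with hCG was asked next. Ranked by the lowest fold over the 4 lists, CNTN3 had the strongest region of all 4 libraries. It lay 29.2 kb from the gene, with 41.7 fold in the control list. GPHN, the gene of the scaffold protein gephyrin (chromosome 14, 67437339 to 67438966), followed with 30.4 fold in the control and 25.5, 52.8 and 42.3 fold in the hCG lists. CYP19A1 (chromosome 15, 51251071 to 51252351, inside the gene) had 20.4 fold in the control list and 31.6, 36.8 and 27.4 fold in the hCG lists. The other regions among the 10 strongest lay in or nearest to NPTX2, ZBTB16 (a pair of regions), RTF1, LOC124903162, NFIA and PEX39. In all of the 10 but that of GPHN, the lowest fold was the control's. In all, 1089 regions held a peak of every library. Of the control peaks, 20.7% (19.6 to 21.8; 1135 of 5484) fell in regions of all 3 hCG libraries, and 42.2% (2315) overlapped a peak of at least 1 hCG library, against at most 2.06% in 100 random placements. Of the regions of all 3 hCG libraries, 14.0% (13.3 to 14.8) held a control peak. The share of 20.7% was 50.1% at a −log10 q of at least 5 and 34.3% at a fold of at least 5, where 544 and 502 regions of all 4 libraries were left. It was 29.5% without hCG replicate 3.

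Regions called in the control alone numbered 3169, or 58.3% of the 5434 regions with a control peak. The 5 with the highest fold lay inside ARHGEF26 (chromosome 3, 154162454 to 154162737, 12.0 fold) and ARHGAP26 (chromosome 5, 142849911 to 142850202, 6.84 fold) or nearest to LOC102724200 (7.55 fold), PLXDC2 (6.86 fold) and the olfactory receptor gene OR2F1 (6.84 fold). Peaks of the control-only regions had a median fold of 4.38 and a median −log10 q of 2.91, and the median fold of the control peaks in regions of all 4 libraries was 5.01. Among steroidogenic genes, 9 of 20 had such a region within 50 kb, among them CYP19A1, FDX1, NR5A1 and HSD3B1, against 3.31 in matched random lists (ratio 2.72, adjusted permutation p = 0.0720). None of the 18 gene lists passed for these regions. At a −log10 q of at least 5, 346 control-only regions were left, 31.6% of the regions with a control peak, and at a fold of at least 5 there were 772, or 52.4%. The share was 80.2% (4366 of 5442) with lists of equal length and 66.5% without hCG replicate 2.

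Which groups of genes lay near the regions of all 3 hCG libraries was tested with 18 gene lists, 16 of them written by hand and all fixed before the data were examined. Steroid receptor response genes stood out, with 15 of 18 members within 50 kb of such a region against 6.65 in matched random lists (ratio 2.26, adjusted permutation p = 0.0018). FKBP5 had 8 regions, the strongest inside the gene (chromosome 6, 35589972 to 35590986) at 44.0, 39.0 and 36.8 fold in the hCG lists and 6.16 fold in the control list. TSC22D3, a glucocorticoid-induced leucine zipper gene, had 7, CRISPLD2 had 4 and PER1, a clock gene, had 2; CDKN1C, HSD11B2 and PGR had none. Genes of steroidogenesis and cholesterol handling followed, with 16 of 20 members against 7.11 (ratio 2.25, adjusted permutation p = 0.0024). This call was lost at a fold of at least 5, with 10 members (ratio 2.14, adjusted permutation p = 0.0612), and with a window of 100 kb (ratio 1.61, adjusted p = 0.0528). SCARB1, a receptor for lipoprotein cholesterol, had 7 regions, CYP11A1, the side-chain cleavage enzyme, had 6, and STAR, which moves cholesterol into mitochondria, had 2. The strongest of this list were near CYB5A, a cytochrome b5 gene (chromosome 18, 74242544 to 74243838; 41.4, 39.0 and 64.5 fold), in CYP19A1, and in HSD3B2 (chromosome 1, 119419260 to 119420086; 25.2, 21.0 and 25.4 fold). INSIG1, SRD5A1 and STARD4 were among the members with no region of all 3, and INSIG1 had no peak in any library. Olfactory receptor genes, which are silent in most tissues, lay far below, with 18 of 392 against 108 (ratio 0.167, adjusted permutation p = 0.0018). OR10H1, OR10H3 and OR10H5 shared 1 region, and OR10A2 was among 234 members with no peak in any library. Members that share regions are not independent, and random lists were not matched on this, so the p for this list may be too small. The p are two-sided, from a permutation test that reassigned list membership 10000 times among genes of like length and density, and adjusted by Benjamini and Hochberg over the 18. The smallest unadjusted p it can give is 0.0002, and genes, not libraries, are its units. Read over regions of the control list, no list passed, with 10 of 18 steroid receptor response genes (ratio 1.98, adjusted permutation p = 0.157) and 11 of 20 steroidogenic genes (ratio 2.17, adjusted p = 0.108); whether the ratios differ between control and hCG was not tested.

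**Figure D5:**
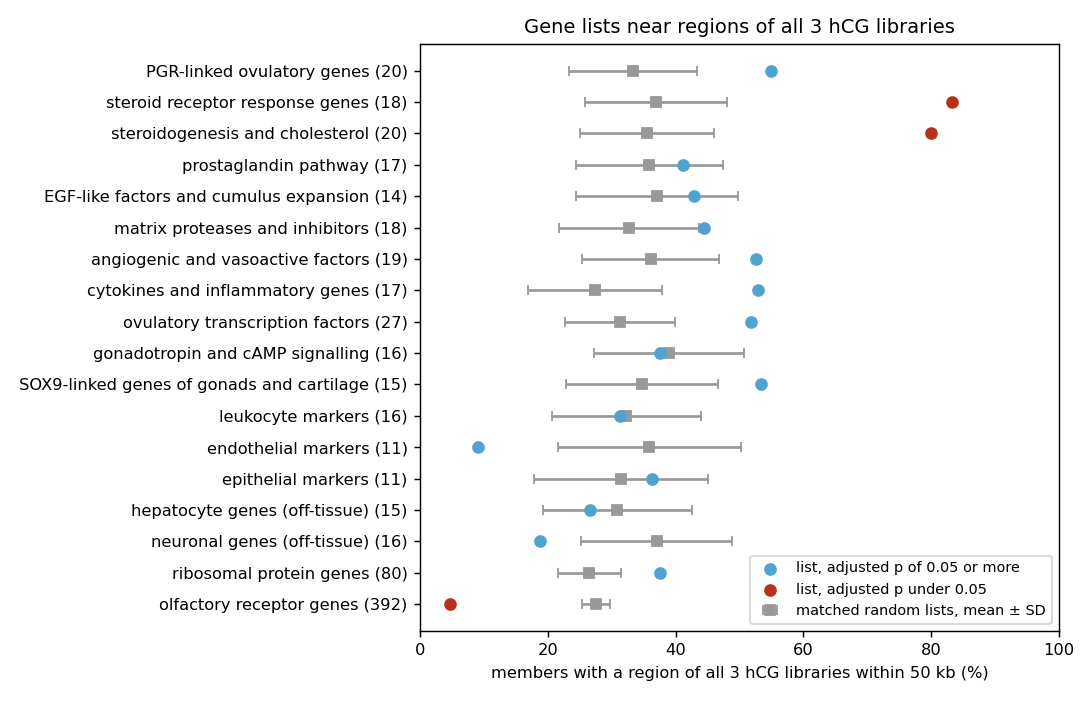
The percentage of each list's measured members (number in brackets) that lie within 50 kb of a region of all 3 hCG libraries is plotted as a point, beside the mean and SD of 10000 matched random lists. The steroid receptor response and steroidogenesis lists lie above and olfactory receptor genes lie below their random lists at an adjusted p under 0.05, and the other 15 lists do not pass. The steroidogenesis call was lost at a fold of at least 5 and with a window of 100 kb.

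The other lists chosen for the ovulating follicle did not pass. Of the 20 PGR-linked ovulatory genes, 11 had a region of all 3 hCG libraries (ratio 1.65, adjusted permutation p = 0.158), among them RUNX1 with 10, EDN2, an endothelin, with 3, EPAS1 with 3, EREG with 2, HIF1A, PPARG, CXCR4, CTSL and SNAP25. The remaining 9, among them PTGS2, the inducible prostaglandin synthase, ADAMTS1, AREG and IL6, each had a region in at least 1 hCG library. That looser count was not set against random lists. PTGS2, AREG and IL6 also had 1 control-only region each within 50 kb. Regions of the control list lay near 10 of the 20 genes (ratio 1.77, adjusted permutation p = 0.235). Cytokines and inflammatory genes counted 9 of 17 (ratio 1.93, adjusted permutation p = 0.117), led by IL1R1 and CCL20 (chromosome 2, 227817925 to 227819706; 26.8, 19.9 and 20.3 fold), and CCL2 had no peak. Ovulatory transcription factors counted 14 of 27 (ratio 1.66, adjusted permutation p = 0.117), with CEBPD at 11.9, 12.3 and 10.9 fold, and EGR1 had no peak. Angiogenic and vasoactive factors counted 10 of 19 (ratio 1.46, adjusted permutation p = 0.328), with TEK, FLT1, a VEGF receptor (36.9, 24.0 and 21.9 fold), and ANGPTL4 (17.1, 15.1 and 14.0 fold). SOX9-linked genes counted 8 of 15 (ratio 1.54, adjusted permutation p = 0.328), with DMRT1 and SOX6, and COL9A1 had no peak. Matrix proteases and inhibitors counted 8 of 18 (ratio 1.36, adjusted permutation p = 0.615), with MMP19 (27.4, 29.1 and 32.9 fold) and TIMP1, and MMP14 had no peak. The prostaglandin pathway (7 of 17, ratio 1.15), EGF-like factors and cumulus expansion (6 of 14, ratio 1.16) and gonadotropin and cAMP signalling (6 of 16, ratio 0.963) had an adjusted p of 1. Examples were PTGES, a prostaglandin E synthase (22.4, 31.9 and 33.1 fold), SDC4 (19.6, 18.1 and 13.1 fold), and PDE7B and PDE4D, both cAMP phosphodiesterases, while PTGDS and INHBB had no peak. The EGFR region inside the gene (6.53, 6.93 and 9.08 fold) lay where the local background reached 10.3 times the lowest of a library.

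Lists for other cell types and tissues gave no call either. Leukocyte markers counted 5 of 16 (ratio 0.969, adjusted permutation p = 1), among them PTPRC, the CD45 gene, and CD14, both with control peaks, and NKG7. Endothelial markers counted 1 of 11, VWF (ratio 0.253, adjusted permutation p = 0.235), and CLDN5 had no peak. Epithelial markers counted 4 of 11 (ratio 1.16, adjusted permutation p = 1), with CLDN3, CLDN4 and PAX8, and EPCAM had no peak. Hepatocyte genes counted 4 of 15 (ratio 0.864, adjusted permutation p = 1), with TF and with APOA1 and APOC3, whose strongest region was the same, while AHSG had no peak. Neuronal genes counted 3 of 16 (ratio 0.506, adjusted permutation p = 0.328), SYN1, CAMK2A and GRIN1, and DLG4 had no peak. The strongest region near SYN1 was the same as that counted for TIMP1 among the matrix inhibitors. Ribosomal protein genes were picked by symbol and include paralogs such as RPL3L, RPL10L and RPL39L. They counted 30 of 80 (ratio 1.41, adjusted permutation p = 0.117), with RPS10, RPL7L1 and RPL37A strongest, and RPL10 was among 13 without a peak. The RPL7L1 region was the same as that named above by PEX39. The local background exceeded 5 times the lowest of a library at PAX8 (7.18), NKG7 (5.26) and GRIN1 (5.04). The gene list calls moved with the window, the fold threshold and the libraries required. With a window of 10 kb cytokines and ovulatory transcription factors also passed above random (adjusted permutation p = 0.0117 and 0.0439). Cytokines passed at a fold of at least 5 as well, with 8 members (ratio 2.75, adjusted permutation p = 0.0360). With 2 hCG libraries required, PGR-linked ovulatory genes and ribosomal protein genes also passed (adjusted permutation p = 0.0270 and 0.0324), and without hCG replicate 3 ribosomal protein genes did (adjusted p = 0.0378).

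The same lists were read over the regions with and without a control peak. Steroid receptor response genes passed for both, with 9 of 18 near regions of all 4 libraries (ratio 6.64, adjusted permutation p = 0.0036), among them FKBP5, PER1, KLF9 and ERRFI1, and 14 of 18 near regions without a control peak (ratio 2.27, adjusted p = 0.0024), among them DUSP1, MT2A and KLF15. Steroidogenesis passed for the regions without a control peak (15 of 20, ratio 2.29, adjusted permutation p = 0.0024), among them STAR, CYP11A1, POR and CYP17A1, and not for those of all 4 libraries (5 of 20, ratio 3.80, adjusted p = 0.109). Olfactory receptor genes lay below random lists in both, with 14 and 7 members. No difference between these region sets was tested for any list.

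Position relative to genes was compared last. Regions of all 3 hCG libraries had their midpoint inside a protein-coding gene in 57.1% of cases, against 42.3% ± 1.11 (mean ± SD of 100 random placements, at most 44.3%). The hCG libraries gave 55.7% ± 0.699 (SD, n = 3) of their peaks and the control 53.5%. Within 1 kb of either end of a coding gene lay 5.31% of the regions of all 3 hCG libraries, 4.16% ± 0.701 (SD, n = 3) of the hCG peaks and 2.43% of the control peaks, against 2.48% ± 0.194 at random. Regions of all 4 libraries were near a gene end less often, 32 of 1089 (2.94%), than regions without a control peak, 380 of 6668 (5.70%; odds ratio 0.501, two-sided Fisher exact test over regions, p = 7.64e-05). This call was lost at a fold of at least 5 (odds ratio 0.698, Fisher exact p = 0.264) and without regions of high local background (odds ratio 0.705, p = 0.130), a setting added after the data were examined.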

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

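No test in this part was chosen after its result was seen, and none was run. The list of hCG replicate 3 held 10 peaks on the mitochondrial genome, which no comparison above used, while the control and hCG replicates 1 and 2 held 0 there.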

How the results depend on the processing

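The removal of regions with high local background, the 50 kb windows from gene ends alone and the thinning were chosen after the data had been examined. The control list stayed shorter than the hCG mean in every setting except lists of equal length, which fix 5484 for all. At a −log10 q of at least 5 there were 1106 control peaks, 16734 hCG peaks on average, 544 regions of all 4 libraries, 346 control-only regions (31.6% of those with a control peak, against 58.3% in the main setting), and 50.1% of control peaks in regions of all 3 hCG libraries. At a fold of at least 5 these were 1482, 8782, 502, 772 and 34.3%, with 4427 regions of all 3 hCG libraries, 3925 of them without a control peak, and an odds ratio near gene ends of 0.698 (Fisher exact p = 0.264). Lists of equal length gave 3546 and 2755 regions and a share of 15.1%, and 80.2% of the regions with a control peak were control-only there. Requiring 2 of 3 hCG libraries gave 18711 and 17105 regions, a share of 30.2% and 4 gene lists above random in place of 2. The share was 17.9% with summits within 200 bp, 19.0% with 50% of the control peak covered, and 19.4% without regions of high background, where the odds ratio was 0.705 (Fisher exact p = 0.130). Windows of 10 kb and 100 kb gave 4 and 1 lists above random. Leaving out an hCG replicate gave 8204 to 17834 regions, 7092 to 16266 without a control peak, and shares of 20.5% to 29.5%, each highest without hCG replicate 3; the odds ratio stayed between 0.481 and 0.602 and past its threshold. Stricter thresholds and fewer required libraries change these counts by construction; the cause was not tested for the odds ratio or the gene lists.

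Olfactory receptor genes stayed below and steroid receptor response genes above random lists, past the threshold, in every alternative run for lists. Of 66 named regions, 60 kept all their libraries at the stricter q, 53 at the stricter fold, 56 with equal lengths and 62 without high background. Read depth was lowest in hCG replicate 3 and next lowest in the control. No paired analysis was possible because the control group has 1 library. Motif, repeat and start-site alternatives were not run, since they need sequence and strand.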

Other observations

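The tests of gene families and the olfactory receptor tests of control-only and single-library regions were chosen after results had been seen, and thinning was added after the data had been examined but before its own result was known. Genes that share the letters of their symbol were tested as 146 families of at least 15 members, in the same way as the lists, and 7 passed after adjustment over the families. Above random lists lay the claudins of tight junctions (15 of 24 CLDN genes near a region of all 3 hCG libraries, ratio 2.16, adjusted permutation p = 0.0389), the ABHD hydrolases (15 of 22, ratio 2.01, adjusted p = 0.0389) and the carbonic anhydrases (12 of 15 CA genes, ratio 2.18, adjusted p = 0.0417). Below lay the ZNF zinc finger genes (114 of 517, ratio 0.629, adjusted permutation p = 0.0146), keratin-associated KRTAP genes (7 of 94, ratio 0.282, adjusted p = 0.0146), CT genes (0 of 25 against 7.16, adjusted p = 0.0195) and PRAMEF genes (0 of 23 against 6.50, adjusted p = 0.0389). Several of these families sit in clusters whose genes share regions, so their members are not independent. No filter on repeats or on how well reads can be placed was run. The counts of 0 therefore do not show a lack of binding.

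The genes with the most regions of all 3 hCG libraries within 50 kb were PRKCH, a protein kinase C gene, with 14, and CLEC16A, NAV2 and TG, the thyroglobulin gene, with 13 each. SMAD3, a mediator of TGF-beta signalling, had 12, GREB1, known as a hormone-responsive gene, had 10, and IL1R2, the decoy receptor of interleukin-1, had 9. In random placements the gene with the most regions held 18.7 on average and at most 29. That maximum was taken over genes of any length, so it cannot judge the count of a shorter gene such as IL1R2 (36.6 kb). No comparison of these counts matched on gene length was run. The genes were named after their counts were seen.

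The control list was shorter than each hCG list. If lower read depth were the cause, hCG replicates 1 and 2 thinned to the control's depth would have come within 1.5 times its length, but the lower of their ratios was 4.95. hCG replicate 3 was longer than the control although it had fewer reads. A lower yield of the one control immunoprecipitation cannot be told apart from an effect of hCG, because there was 1 control library. More PGR-bound sites after hCG may therefore be offered only as a hypothesis.

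hCG replicate 3 had fewer peaks than hCG replicates 1 and 2. Thinned to its depth, these still gave 2.23 and 2.50 times as many peaks, which argues against lower depth as the whole cause. Part of the gap went, but the −log10 p threshold of 3.95 was also stricter than the smallest values in their own lists, 3.42 and 3.29. How much of the fall came from depth is therefore not known. Its peaks lay mostly within theirs, at 86.8% and 86.7%. A weaker immunoprecipitation and a difference between cell preparations could both remain as causes and were not tested.

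In the full lists 58.3% of the regions with a control peak held no hCG peak, a share that was 31.6% at a −log10 q of at least 5, 52.4% at a fold of at least 5, 80.2% with lists of equal length and 58.7% to 66.5% with an hCG replicate left out. Weak calls near the threshold are a candidate explanation. The share of control peaks overlapping an hCG peak was 47.6 percentage points higher in the strongest quintile by −log10 q than in the weakest. Overlap with both other hCG lists also fell with strength in each hCG list, from 81.2% to 2.29% in replicate 1. The gradient therefore cannot tell weak calls from other explanations. Placement without regard to silent genes was proposed only after olfactory receptor genes were seen to hold control-only regions at a ratio of 1.10 to random lists, so that value cannot tell. Regions of hCG replicate 1, 2 or 3 alone gave lower ratios of 0.552, 0.510 and 0.278, but their peaks were stronger, with a median −log10 q of 4.58, 3.96 and 4.25 against 2.91, and no difference was tested. Loss of PGR from some sites after hCG was not tested and stays open.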
